A study of Mus musculus with 14 samples.

How the data were processed

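RNA from sorted mouse CD4 T cells was measured on 14 single-colour Agilent arrays. The cells carry B5, a transgenic T cell receptor that recognises an antigen of the malaria parasite Plasmodium chabaudi. The samples fall into 7 groups of 2 replicates from different donors: naive cells, 3 effector subsets sorted on day 8 of infection, and 3 memory subsets sorted on day 60. For the memory samples 1 label field gives day 8 of infection, while the series design and the treatment protocol give day 60, and day 60 was used. Per the labels' protocols, cells bearing CD8a, B220, CD11b, CD11c, F4/80 or Ter119 were depleted before the sort. Effector cells were CD44 intermediate to high and CD127 negative, and memory cells were CD44 high and CD127 high. CD62L and CD27 then separated early, intermediate and late effector cells, and central memory, early effector memory and late effector memory cells.

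The authors labelled the RNA with Cy3 and read it with Agilent Feature Extraction 10.7.3.1, per the file headers and the labels' protocols. The scanner files deposited for each array hold the spot intensity, the local background intensity and a processed signal, which per the file headers is corrected for background and spatial trend within 1 array. The deposited series table holds linear intensity values with nearly the same distribution on all arrays except at the top. Their maximum was 62669.3 to 66728.9 on the replicate 2 arrays of effector cells and near 200546.6 on the others. The submitters' processing notes name R 2.12.1, and the method of that step is not stated.

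The processed signal was the starting point here. Spots marked as outliers were left out, spots of 1 probe were averaged, and the 75th percentile of each array was subtracted on the log2 scale, so a level of 0 is that percentile. Of the 55681 probes, 28288 matched exactly 1 gene symbol of a RefSeq gene reference. A gene was read from its probe with the highest mean level, which left 21321 genes. The other 20 gene symbols had no probe measured on all arrays. Symbols are those of that reference, found through the transcript that the array annotation names for each probe. The files name the mouse genome build mm9 and the reference table at hand is for GRCm38.p6, so no coordinates are given. Among the probes, 5516 carried different accessions in the 2 annotation versions of the files. A gene was tested in a comparison when both arrays of at least 1 compared group were marked well above background, and 12391 genes were tested in at least 1 comparison. Between 38.6% and 43.8% of probes passed that mark on 11 arrays, and 57.2% to 60.2% on the 3 arrays of slide 2. The saturation value in the file headers was 65530 on slide 2 and 671748 to 779637 on the other arrays. On slide 2 608 to 680 probes per array were saturated, against 0 elsewhere. In replicate 2 this difference cannot be told apart from that of effector against memory or naive cells. The number of arrays limits the precision.

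Changes were fitted with limma 3.58.1 in R 4.3.3, with the data.table package at version 1.17.8, as differences between the 7 group means, with 7 residual degrees of freedom, and p values were adjusted by the Benjamini-Hochberg method across the genes tested. A gene was called at an adjusted p under 0.05. All adjusted p values are two-sided and from limma. The arrays come from 3 slides. Slide 1 holds every replicate 1, slide 2 holds the replicate 2 arrays of the effector subsets and slide 3 those of the memory and naive cells. Samples with the same replicate number deviated together from their group means: over 12391 genes the correlation was 0.454 to 0.915 in the 21 pairs of groups, and at least 0.485 where both replicate 2 arrays shared a slide. The numbers thus appear to pair the samples. The main fit has no block, so its counts, standard errors, adjusted p values and list tests leave this pairing out. Fits with the slide or the replicate number as a block are given beside it for the counts over all genes. For gene lists the counts with a slide block are given where they moved by more than 1.5 times. Effector cells meet naive or memory cells on slide 1 alone, so for those comparisons the fit with a slide block rests mainly on slide 1.

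Gene lists, 27 in number with 439 members, were tested with camera in limma at a preset correlation of 0.01, and again with an estimated correlation, without a block and with slide as a block. Each list result gives the members tested, those called over all genes, and those called when adjusted over the list alone. The alternatives of a list test are an estimated correlation, a slide or replicate block, normexp correction, and a slide block with an estimated correlation. Where one group lies at background, the fold is a lower bound against the level at which signal counts as well above background, and list medians are also given with such genes at their bound.

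The groups, comparisons, lists, the rule for naming genes and most alternatives were chosen before the data were examined, and 6 alternatives were added after. The rule names, in each of the 5 main comparisons, the 6 largest rises and 6 largest falls among called genes that were well above background, unsaturated and without overlap between the replicates of the groups, and 3 of each in the steps between neighbouring subsets. It also names the 3 members with the smallest p of each called list and of the fatty acid synthesis list, and genes of the sort markers, among them Cd27, Il7r (CD127), Cd44, Il2ra and Cd4. No gene met the rule in the comparisons of subsets without a block, so it was applied there to the fit with a slide block after the values were seen.

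The alternatives changed the background correction, the scaling between arrays, the filter, the block, the choice of probe, the set of arrays or the input values, and left out each array in turn. The normexp background correction was planned on mean spot intensity, which the files do not hold, and used the median spot intensity with an offset of 50. The fits were tested on simulated data with known changes, after they had first been run on the arrays. Principal components used 9737 genes. Figures were drawn in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Probes with no symbol or several symbols were left out of the gene comparisons.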

Results

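Gene expression was measured in naive B5 CD4 T cells (2 arrays), in 3 effector subsets taken on day 8 of Plasmodium chabaudi infection and in 3 memory subsets taken on day 60 (2 arrays for each subset). Naive cells have not met antigen, effector cells are dividing and acting against the parasite, and memory cells remain after the infection is controlled. Between 38.6% and 60.2% of probes on an array were well above background. Levels below are log2 signal relative to the 75th percentile of the array, and changes are log2 differences of group means ± standard error from limma.

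The largest separation of the arrays was by slide, ahead of cell type. Over 9737 genes the first principal component held 43.2% of the variance and parted the slides, and the second held 30.1%. Replicates of 1 group correlated at 0.920 to 0.956 over genes, while different groups on slide 1 correlated at 0.893 to 0.992. Il7r, which encodes CD127, was higher in memory than in effector cells, and Ifng, encoding interferon gamma, was near 5 in antigen-experienced cells and below 0 in naive cells. Cd27, a marker used to sort the subsets, was not called in any main comparison, at 0.09 ± 0.59 between late and early effector (−0.13 with the median of each array as the scale) and −0.89 ± 0.59 between late effector memory and central memory cells. In memory cells the step from central memory to early effector memory ran in opposite directions in the replicates, with a correlation of −0.572 over 10887 genes. Comparisons of the memory subsets take each library by its label, with this disagreement open.

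**Figure D1:**
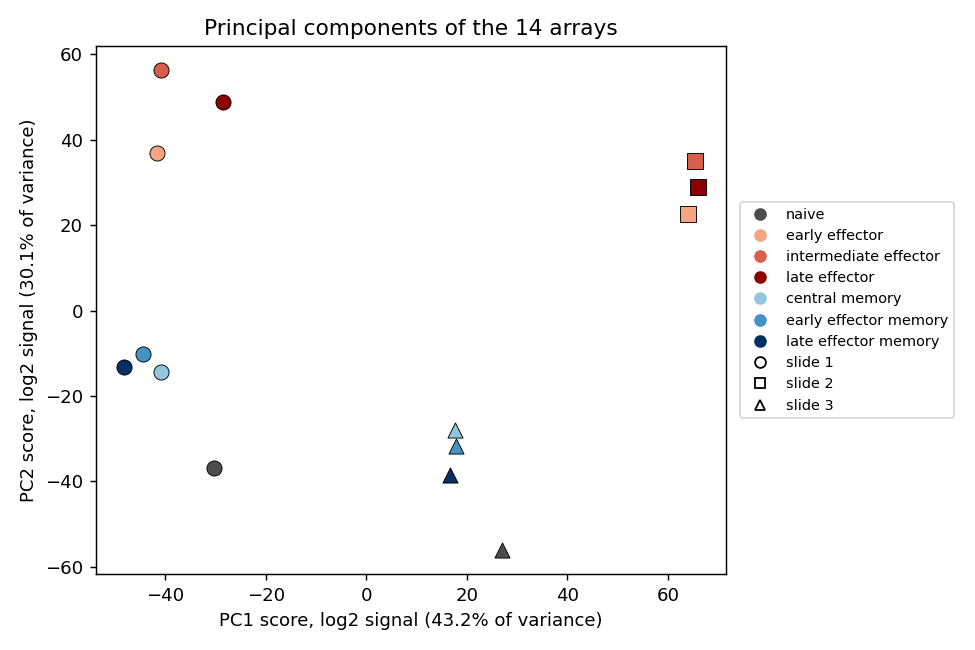
The 14 arrays on the first 2 principal components of log2 signal over 9737 genes, coloured by group with the marker showing the slide. The first component holds 43.2% and the second 30.1% of the variance, and the slides stand apart.

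**Figure D2:**
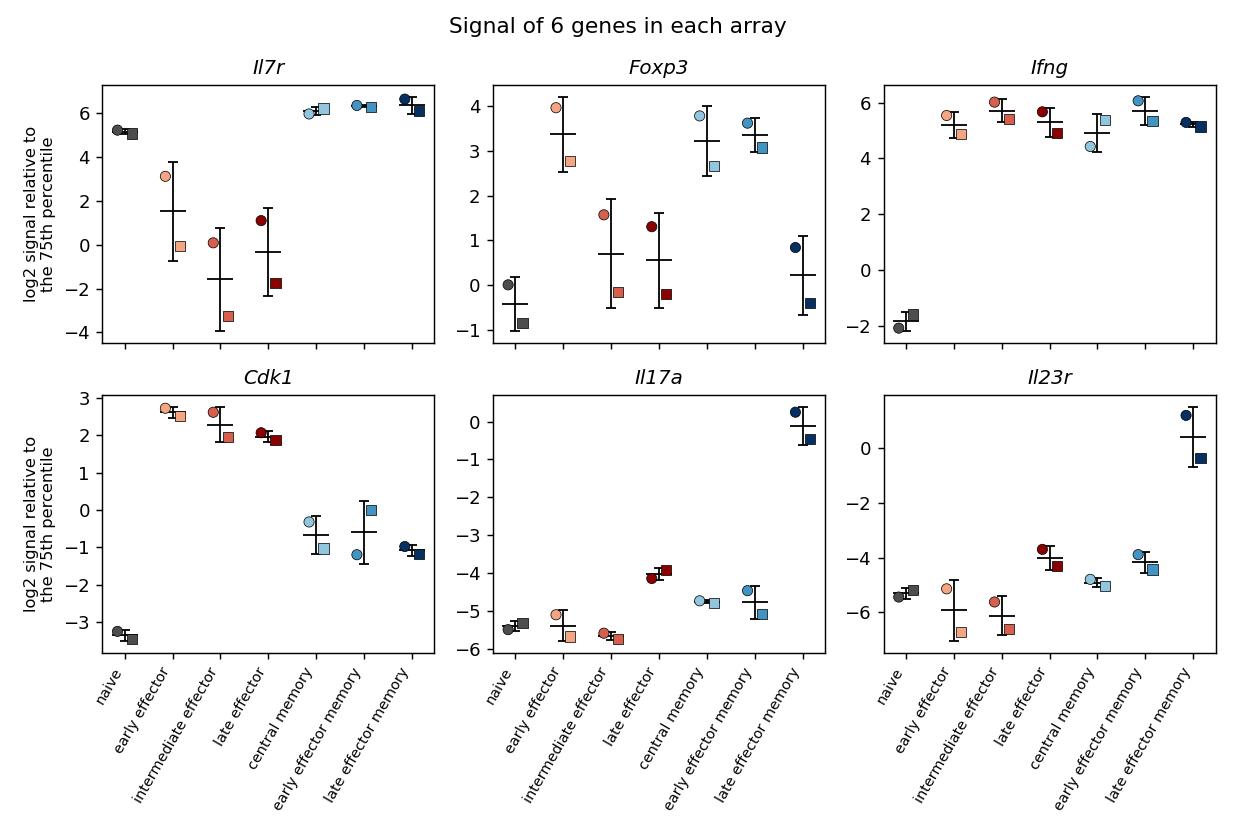
Log2 signal relative to the 75th percentile of the array for 6 genes in the 7 groups, with circles for replicate 1, squares for replicate 2, and the mean with its standard deviation. Ifng is high in the effector and memory groups, and Il17a and Il23r rise in late effector memory cells alone.

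Effector cells were compared with naive cells to see what infection had changed by day 8. The cell cycle, Th1, follicular helper and inhibitory receptor lists were higher in effector cells, as was glycolysis by less, and the naive and quiescence list was lower. These calls were lost with an estimated correlation, in that order at adjusted p = 0.0845, 0.213, 0.213, 0.0845, 0.507 and 0.213 with an estimated correlation. Erythroid and platelet markers were higher as well (median 1.56, adjusted p = 0.0104, and adjusted p = 0.146 with an estimated correlation). Of 12175 genes tested, 893 were higher and 482 lower in effector cells. With slide as a block 2631 were higher and 1836 lower, and with replicate number as a block 1726 were higher and 1795 lower. The naive arrays decided many calls: 391 genes were higher and 92 lower without naive replicate 1, and 413 higher and 105 lower without naive replicate 2. Of the called genes 64.9% were higher, against 49.3% with the deposited values.

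Under the naming rule the largest rises in effector cells were in Ifng (7.24 ± 0.42, adjusted p = 1.94e-05), the chemokine receptors Cxcr3 (7.02 ± 0.58, adjusted p = 9.18e-05) and Cxcr5 (6.51 ± 0.78), Gpm6b (6.28 ± 0.97), the vesicle protein Sytl3 (6.17 ± 0.61) and Cd83 (5.95 ± 0.72). The largest falls were in Vipr1 (−6.22 ± 0.65, adjusted p = 0.000241), Tdrp (−5.71 ± 0.82), the complement regulator Cd55 (−5.62 ± 0.54), Dapl1 (−6.08 ± 1.15), Il7r (−5.28 ± 0.998) and Igfbp4 (−5.14 ± 1.06). The call on Dapl1 was lost without naive replicate 1 (−5.60). The calls on Il7r and Igfbp4 were lost without either naive array, at −5.20 and −5.36 for Il7r and −4.69 and −5.58 for Igfbp4. Of 34 tested cell cycle genes 29 rose and 0 fell, or 32 and 0 adjusted over the list alone, with a median change of 3.41 (3.11 with genes at background set to their bound). Cdk1 was at least 42.3-fold higher, Tpx2 at least 16.9-fold and Bub1b at least 14.9-fold. Of 16 follicular helper genes 11 rose and 0 fell (13 and 0 adjusted over the list alone, median 3.55), led by Il21, at least 525-fold higher, with Maf (5.33 ± 0.67). Of 13 Th1 genes 8 rose and 1 fell (11 and 2 adjusted over the list alone, median 2.74), including Tbx21 (5.89 ± 0.71).

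Effector molecules and inhibitory receptors were both higher as lists at the preset correlation (adjusted p = 0.202 and 0.0845 with an estimated correlation). Of 18 effector molecules 9 rose and 0 fell (12 and 1 adjusted over the list alone, median 2.13). Among them were Gzmb (6.31 ± 0.75) and Il10, at least 42.1-fold higher. Gzmb rose by more than some genes named as largest rises but did not meet the rule for them, so its change may not be exact. Of 10 inhibitory receptors 7 rose and 0 fell (7 and 0 adjusted over the list alone, median 3.63, or 2.80 with bounds). They included Lag3 (8.94 ± 0.71) and Nt5e (3.31 ± 0.34). Lag3 rose by more than the genes named as largest rises but did not meet the rule for them, so its change may not be exact. Of 11 effector transcription factors 9 rose and 0 fell (9 and 0 adjusted over the list alone, median 2.27), with Bhlhe40 (4.80 ± 0.57) and Irf4 (3.93 ± 0.45). Of 12 regulatory T cell genes 7 rose and 0 fell (8 and 0 adjusted over the list alone, median with bounds 2.41), with Ikzf2 (5.30 ± 0.59), Lrrc32 (4.52 ± 0.62) and Il2ra (4.17 ± 0.66). Of 9 Th2 and Th17 genes 4 rose and 0 fell (4 and 0 adjusted over the list alone, median 2.90, or 1.34 with bounds), and Il4 was at least 51-fold higher. Of 18 naive and quiescence genes 0 rose and 13 fell (0 and 15 adjusted over the list alone, median −2.37). They included Klf2 (−3.09 ± 0.51), whose call was lost without naive replicate 1 (−2.62), and Bach2 (−2.85 ± 0.52), whose call was lost without naive replicate 1 (−2.95) and without naive replicate 2 (−2.75).

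The metabolic lists called had medians smaller in size than these lists, and that difference was not tested. Of 19 glycolysis genes 5 rose and 0 fell (5 and 0 adjusted over the list alone, median 0.93), with Slc16a3 (4.88 ± 0.77) and Tpi1 (3.16 ± 0.45), and with slide as a block 16 rose and 0 fell. Of 15 amino acid and one-carbon genes 2 rose and 0 fell (3 and 0 adjusted over the list alone, median 0.45), with Asns (3.92 ± 0.71), whose call was lost without naive replicate 1 (3.50). Of 22 cholesterol genes 1 rose and 2 fell (1 and 2 adjusted over the list alone, median −0.57). These 3 lists, the 8 lists of immune genes above and the cell cycle list were called by camera. Their adjusted p was 1.37e-29 for the cell cycle, 3.17e-11 for follicular helper genes, 3.17e-11 for naive genes, 1.33e-07 for inhibitory receptors, 1.55e-07 for effector transcription factors, 1.29e-06 for Th1 genes, 1.60e-06 for effector molecules, 3.12e-06 for regulatory T cell genes, 0.000103 for glycolysis, 0.00387 for Th2 and Th17 genes, 0.0104 for amino acid genes and 0.0224 for cholesterol genes. None was called with an estimated correlation, with or without a slide block. In the same order adjusted p = 0.0845, 0.213, 0.213, 0.0845, 0.130, 0.213, 0.202, 0.307, 0.507, 0.507, 0.593 and 0.782 with an estimated correlation, and the highest adjusted p of each list over its alternatives was 0.232, 0.321, 0.271, 0.232, 0.232, 0.213, 0.232, 0.307, 0.507, 0.507, 0.593 and 0.782. The members called with a slide block were 9 higher and 1 lower for amino acid genes, 1 and 10 for cholesterol genes, 7 and 0 for Th2 and Th17 genes, and 8 and 1 for inhibitory receptors.

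**Figure D3:**
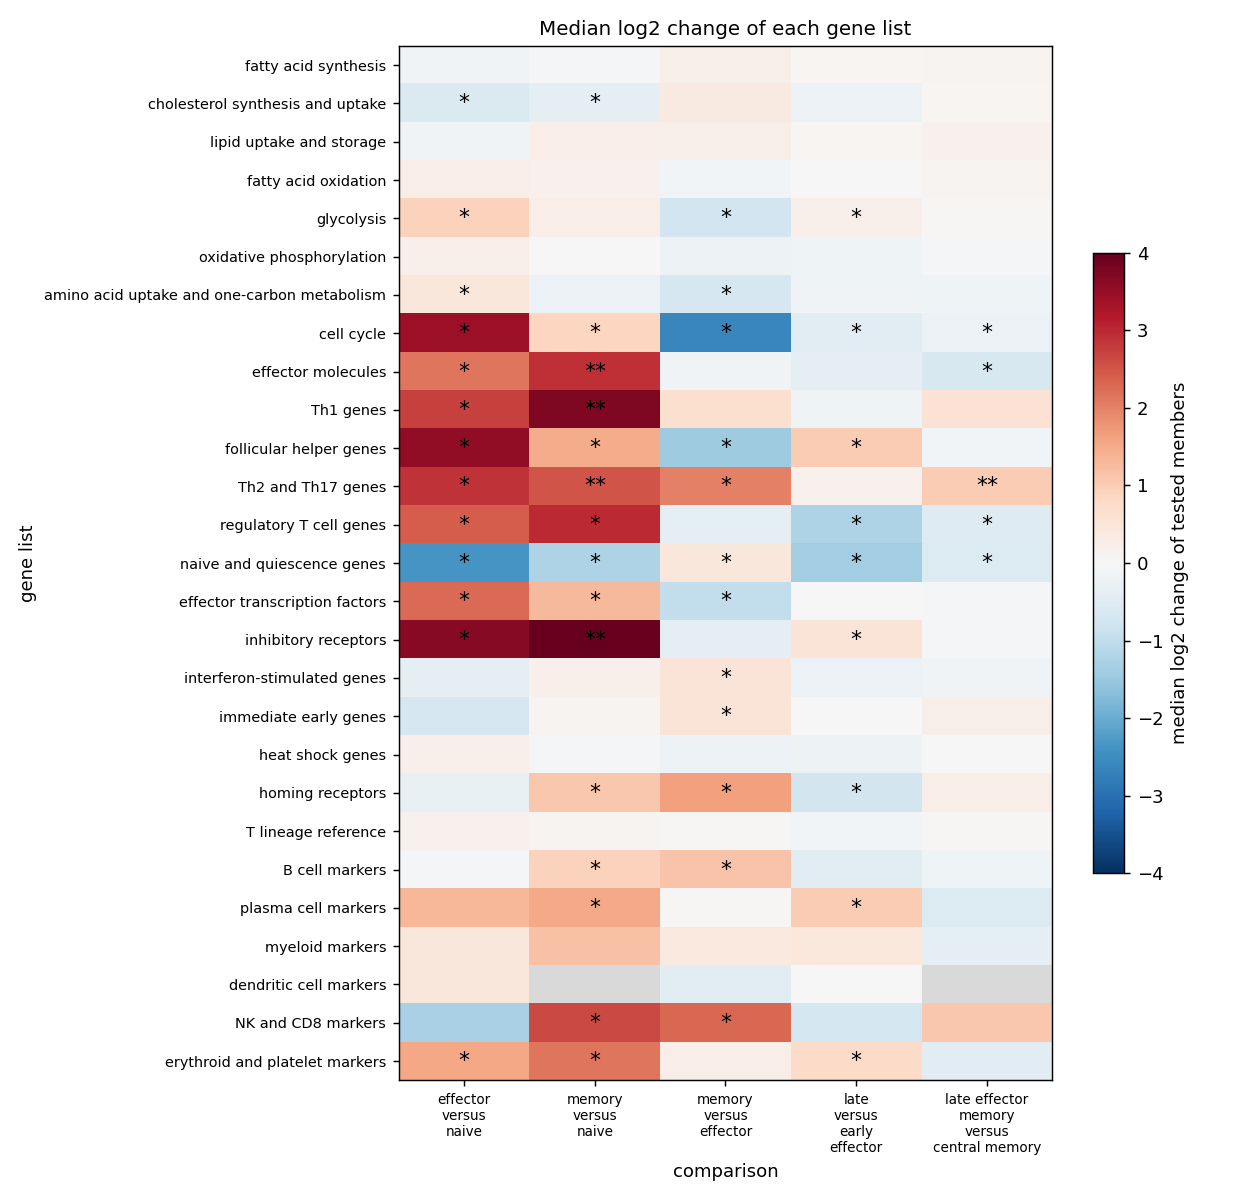
Median log2 change of the tested members of each gene list in the 5 main comparisons, with grey where no member was tested. A star marks lists called by camera at the preset correlation of 0.01 and a double star those also called with an estimated correlation. Cell cycle genes are high against naive in effector cells with a median of 3.41 and low in memory against effector cells with a median of −2.59.

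Memory cells were compared with naive cells to see what stayed changed at day 60. The Th1, effector molecule, Th2 and Th17 and inhibitory receptor lists were higher in memory cells. Marker lists of other cells were also called higher: NK and CD8 (median 2.64, adjusted p = 0.00996), B cell (0.92, adjusted p = 0.0303), plasma cell (1.53, adjusted p = 0.00839) and erythroid and platelet markers (adjusted p = 0.000161). These marker calls were lost with an estimated correlation, in that order at adjusted p = 0.293, 0.311, 0.110 and 0.110. Of 11709 genes tested, 511 were higher and 54 lower, so 90.4% of called genes were higher, against 74.7% with the deposited values. With slide as a block 1328 were higher and 619 lower, and with replicate number as a block 868 and 248. The naive arrays decided these counts: 168 genes were higher and 3 lower without naive replicate 1, and 168 higher and 5 lower without naive replicate 2. The number lower was also 31 without early effector memory replicate 1, 32 without late effector memory replicate 1 and 34 without late effector memory replicate 2.

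By the same rule the largest rises in memory cells were in Cxcr3 (7.67 ± 0.58, adjusted p = 0.000132), Ifng (7.11 ± 0.42, adjusted p = 2.26e-05), S100a4 (7.10 ± 0.98), S100a6 (7.05 ± 0.84), Il1rl1, the receptor for interleukin 33 (6.72 ± 0.62), and Gpm6b (6.71 ± 0.97), whose call was lost without naive replicate 2 (5.97). The largest falls were in Igfbp4 (−4.74 ± 1.06), Xkrx (−3.96 ± 0.77), Adh1 (−3.69 ± 0.90), Treml2 (−3.38 ± 0.74), Cnn3 (−3.03 ± 0.71) and H2-Ob (−2.90 ± 0.68). All 6 of these calls were lost without naive replicate 1, at −4.29, −3.89, −3.59, −3.41, −2.61 and −2.72, and without naive replicate 2, at −5.19, −4.04, −3.79, −3.36, −3.46 and −3.07. All of them except Xkrx were also lost with only the arrays of the compared groups. Of 11 Th1 genes 7 rose and 0 fell (10 and 0 adjusted over the list alone, median 3.73, or 2.38 with bounds), with Tbx21 (6.55 ± 0.71) and Il12rb1 (3.73 ± 0.44). Of 18 effector molecules 10 rose and 0 fell (12 and 0 adjusted over the list alone, median 2.92, or 1.95 with bounds), and Klrg1 was at least 73.4-fold higher. Of 13 Th2 and Th17 genes 9 rose and 0 fell (9 and 0 adjusted over the list alone, median 2.53, or 1.62 with bounds), with Ccr6 (5.99 ± 0.72). Of 9 inhibitory receptors 6 rose and 0 fell (7 and 0 adjusted over the list alone, median 4.22, or 3.90 with bounds), with Nt5e (4.37 ± 0.34). These 4 lists were called by camera at adjusted p = 7.96e-16, 1.55e-13, 6.52e-13 and 3.16e-09, and each was also called with an estimated correlation and no block (adjusted p = 0.0436). That was the highest value over the alternatives for Th1 genes, effector molecules, and Th2 and Th17 genes. The inhibitory receptor call was lost with an estimated correlation and a slide block (adjusted p = 0.188, its highest value), and with that block 7 of its members were higher and 1 lower.

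Further lists were called in memory cells at the preset correlation but not with an estimated one without a block. Of 11 regulatory T cell genes 5 rose and 0 fell (9 and 0 adjusted over the list alone, median with bounds 2.90), with Ikzf2 (4.41 ± 0.59) and Nrp1, at least 7.44-fold higher (adjusted p = 3.04e-11 for the list, and adjusted p = 0.110 with an estimated correlation, 1.09e-13 to 0.110 over the alternatives). That list was called with an estimated correlation once slide was a block (adjusted p = 0.0430), and the others here were not. Of 18 naive and quiescence genes 0 rose and 6 fell (0 and 10 adjusted over the list alone, median −1.24, adjusted p = 3.08e-11, and adjusted p = 0.186 with an estimated correlation, 1.51e-17 to 0.380 over the alternatives). Of 15 follicular helper genes 5 rose and 0 fell (8 and 0 adjusted over the list alone, median 1.47, adjusted p = 8.66e-08, and adjusted p = 0.283 with an estimated correlation, 5.14e-09 to 0.380 over the alternatives), and Il21 was at least 41.8-fold higher. Of 30 cell cycle genes 6 rose and 0 fell (12 and 1 adjusted over the list alone, median 0.86, or 0.62 with bounds, adjusted p = 1.64e-07, and adjusted p = 0.287 with an estimated correlation, 3.26e-06 to 0.420 over the alternatives). Of 11 effector transcription factors 3 rose and 0 fell (5 and 0 adjusted over the list alone, median 1.29, adjusted p = 1.75e-06, and adjusted p = 0.110 with an estimated correlation, 7.62e-08 to 0.188 over the alternatives), with Bhlhe40 (4.46 ± 0.57). Of 13 homing receptors 3 rose and 0 fell (4 and 0 adjusted over the list alone, median 1.08, adjusted p = 0.000104, and adjusted p = 0.293 with an estimated correlation, 4.19e-06 to 0.293 over the alternatives), with Itgb1 (4.72 ± 0.59) and Ccr2, at least 59.6-fold higher. The 22 cholesterol genes had 0 calls, also adjusted over the list alone, or 2 higher and 7 lower with slide as a block, with a median of −0.39 (adjusted p = 0.00986, and adjusted p = 0.739 with an estimated correlation, 0.00110 to 0.739 over the alternatives). A slide block called 10 regulatory T cell, 9 follicular helper, 14 cell cycle, 7 effector transcription factor and 6 homing receptor genes higher and 12 naive and quiescence genes and 1 cell cycle gene lower. Glycolysis, with 1 gene higher, or 2 higher and 1 lower with a slide block, was called with a slide block only (adjusted p = 0.137 without a block, and 0.00376 to 0.851 over the alternatives, and adjusted p = 0.380 with both a slide block and an estimated correlation).

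Many genes were called against naive in both effector and memory cells. Among the 11493 genes tested against naive in both, 715 were higher in effector and 462 in memory cells, and 354 were higher in both. Independent lists of those sizes would share 28.7. Genes lower in both numbered 45, from 482 and 54, where independent lists would share 2.26. Over 50 simulations with no change in any group and redrawn naive arrays used in both comparisons, a mean of 0 genes was shared. Few genes are called where nothing changes, so this value does not measure what shared controls add. The simulated value leaves out the effects and that of independent lists leaves out the shared controls. The 2 naive arrays could not be split, so part of the excess may come from shared controls. With a slide block 937 genes were higher and 420 lower in both, and with a replicate block 619 and 200. Genes higher in both numbered 110 without naive replicate 1 and 105 without naive replicate 2. Genes lower in both numbered 0 without naive replicate 1, 3 without naive replicate 2, 26 without early effector memory replicate 1 or late effector memory replicate 1, and 28 without late effector memory replicate 2. Without a block 1 gene was called in opposite directions, against 34 with slide and 14 with replicate number as a block. It was Acsbg1, an acyl-CoA synthetase, which fell in effector cells (−1.32 ± 0.38) and rose in memory cells (2.10 ± 0.38) and was singled out after its values were seen.

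Memory cells were compared with effector cells to see what separates day 60 from day 8. The cell cycle list was lower in memory than in effector cells, as were glycolysis and follicular helper genes with fewer members called. The homing receptor and the Th2 and Th17 lists were higher. These 5 calls were lost with an estimated correlation, in that order at adjusted p = 0.128, 0.634, 0.594, 0.607 and 0.577. NK and CD8 markers (median 2.31, adjusted p = 0.00962, and adjusted p = 0.594 with an estimated correlation) and B cell markers (median 1.155, adjusted p = 0.0441, and adjusted p = 0.607 with an estimated correlation) were higher as well. Effector molecules and Th1 genes were not called as lists, with members in both directions. Of 12277 genes tested, 907 were higher and 645 lower, and 793 and 600 of these by at least 2-fold. With slide as a block 1755 were higher and 2313 lower, which took the share higher from 58.4% to 43.1%, and with replicate number as a block 2564 and 1754. The number higher was 595 without intermediate effector replicate 2, 599 without late effector memory replicate 1 and 601 without early effector replicate 2.

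The naming rule gave the largest rises in Il7r (6.39 ± 0.70, adjusted p = 0.000296), Il18r1 (4.75 ± 0.34, adjusted p = 5.13e-05), Ccr6 (4.65 ± 0.51), Tdrp (4.49 ± 0.58), Cpne7 (4.42 ± 0.51) and Tmem37 (4.22 ± 0.48). The largest falls were in Fhdc1 (−4.25 ± 0.26, adjusted p = 2.11e-05), Lag3 (−4.13 ± 0.50), Il21 (−3.65 ± 0.57), the anion carrier Slco4a1 (−3.58 ± 0.39), Sapcd2 (−3.58 ± 0.42) and Ska1 (−3.28 ± 0.29). Of 34 cell cycle genes 0 rose and 31 fell (0 and 32 adjusted over the list alone, median −2.59, or −2.48 with bounds), with Cdk1 (−3.08 ± 0.29) and Bub1b (−3.87 ± 0.32). Of 16 follicular helper genes 0 rose and 6 fell (0 and 11 adjusted over the list alone, median −1.41), with Tox2 (−2.04 ± 0.38). Of 19 glycolysis genes 0 rose and 6 fell, also adjusted over the list alone, or 17 fell with slide as a block (median −0.76), with Slc16a3 (−3.16 ± 0.55) and Tpi1 (−2.71 ± 0.32). Of 15 amino acid and one-carbon genes 0 rose and 2 fell, also adjusted over the list alone (median −0.66), with Shmt1 (−2.45 ± 0.30). Of 11 effector transcription factors 1 rose and 5 fell (1 and 6 adjusted over the list alone, median −0.98). Of 14 Th2 and Th17 genes 9 rose and 0 fell (10 and 1 adjusted over the list alone, median with bounds 1.34), with Il1rl1 (3.82 ± 0.44). Of 13 homing receptors 7 rose and 0 fell (9 and 0 adjusted over the list alone, median 1.64). They included Ccr10 (6.57 ± 0.49), Itga4 (2.70 ± 0.26) and Itgb7 (2.13 ± 0.32). Ccr10 and Bub1b changed by more than some genes of the naming rule but did not meet it, so their changes may not be exact. Of 18 naive and quiescence genes 5 rose and 0 fell, also adjusted over the list alone (median 0.45), with Klf2 (2.53 ± 0.36) and Klf3 (1.60 ± 0.26).

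The immediate early and interferon lists were called higher in memory cells without a block at the preset correlation, with a minority of their members called (adjusted p = 0.690 and 0.769 with an estimated correlation). Of 19 immediate early genes 5 rose and 0 fell, also adjusted over the list alone (median 0.52), with Klf6 (2.73 ± 0.30) and Ier2 (1.59 ± 0.29), and of 23 interferon-stimulated genes 5 rose and 1 fell, also adjusted over the list alone (median 0.51), with Oas1a (1.56 ± 0.22). Camera called these lists at adjusted p = 1.04e-30 for the cell cycle, 1.15e-06 for follicular helper genes, 2.29e-05 for Th2 and Th17 genes, 8.32e-05 for glycolysis, 9.24e-05 for amino acid genes, 0.000394 for homing receptors, 0.00117 for effector transcription factors, 0.0103 for naive genes, 0.0322 for interferon-stimulated genes and 0.0404 for immediate early genes. None was called with an estimated correlation, with or without a slide block. In the same order adjusted p = 0.128, 0.594, 0.577, 0.634, 0.594, 0.607, 0.594, 0.769, 0.769 and 0.690 with an estimated correlation, and the highest adjusted p over the alternatives was 0.338, 0.594, 0.577, 0.634, 0.594, 0.607, 0.594, 0.769, 0.858 and 0.690. In the fit with a slide block the members called were 0 higher and 12 lower for follicular helper genes, 0 and 11 for amino acid genes, 10 and 2 for Th2 and Th17 genes, 1 and 8 for effector transcription factors, 8 and 1 for homing receptors, 4 and 2 for interferon-stimulated genes and 10 and 1 for immediate early genes. The interferon list was not called with slide (adjusted p = 0.277) or replicate number (0.0786) as a block, within 0.0461 to 0.858 over its alternatives. Its median on slide 1 alone was −0.03. The immediate early list was not called with a replicate block (adjusted p = 0.0797, within 5.23e-05 to 0.690). Lists that camera did not call were the effector molecules (7 higher and 5 lower of 18, median −0.13, adjusted p = 0.953), Th1 genes (3 and 3 of 13, median 0.65, adjusted p = 0.575), inhibitory receptors (1 and 3 of 10, adjusted p = 0.236), regulatory T cell genes (1 and 2 of 12, or 2 and 4 with a slide block, adjusted p = 0.830) and cholesterol genes (3 and 1 of 22, or 7 and 3 with a slide block, median 0.35, adjusted p = 0.523).

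Late effector cells were compared with early effector cells to see how the subsets part during the acute response. Naive and quiescence genes, regulatory T cell genes, homing receptors and cell cycle genes were lower in late effector cells as lists, while follicular helper genes and inhibitory receptors were higher, with 0 members called without a block. These calls were lost with an estimated correlation, in that order at adjusted p = 0.343, 0.343, 0.471, 0.556, 0.395 and 0.343. Plasma cell markers (median 1, adjusted p = 0.0334, and adjusted p = 0.343 with an estimated correlation) and erythroid and platelet markers (median 0.75, adjusted p = 0.0444, and adjusted p = 0.395 with an estimated correlation) were higher as well. Of 11812 genes limma called 0, with 279 at an unadjusted p under 0.05. With slide as a block 8 were higher and 5 lower (1213 at an unadjusted p under 0.05), and with replicate number as a block 3 higher and 1 lower. With a slide block the higher genes included Ntrk3 (3.12 ± 0.22), Pde3b (1.78 ± 0.20), Cdh23, Cpeb1, Cyp11a1, Fam71b and Grp. The lower genes were the regulatory T cell factor Foxp3 (−2.82 ± 0.23), Ikzf4 of the same gene list (−2.08 ± 0.23), She (−2.06 ± 0.21), Itih5 (−1.82) and Chst10 (−1.66). These genes were chosen after their values were seen.

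The lists that differed between late and early effector cells had 0 members called over all genes without a block, and 0 adjusted over the list alone except where given. The 18 naive and quiescence genes had a median of −1.38 (−1.61 on slide 1 and −1.12 on slide 2, adjusted p = 2.64e-14, and adjusted p = 0.343 with an estimated correlation, 6.29e-19 to 0.664 over the alternatives), with Bach2 at −1.95 ± 0.63. The 12 regulatory T cell genes had a median of −1.22 (−0.98 and −1.47 on slides 1 and 2), with 0 higher and 4 lower adjusted over the list alone and 2 lower with slide as a block (adjusted p = 2.54e-11, and adjusted p = 0.343 with an estimated correlation, 1.30e-13 to 0.343 over the alternatives), among them Lrrc32 at −3.18 ± 0.75 and Il2ra at −2.28 ± 0.80. The 16 follicular helper genes had a median of 1 and a mean of 1.19 (medians of 1.03 and 1 on slides 1 and 2, adjusted p = 1.44e-08, and adjusted p = 0.395 with an estimated correlation, 8.63e-13 to 0.664 over the alternatives), with Ascl2 at 3.96 ± 1.61 and Bcl6 at 2.41 ± 0.80. The 34 cell cycle genes had a median of −0.42 (adjusted p = 0.000222, and adjusted p = 0.556 with an estimated correlation, 5.73e-07 to 0.755 over the alternatives), and the 11 homing receptors one of −0.74 (adjusted p = 0.000417, and adjusted p = 0.471 with an estimated correlation, 0.000221 to 0.471 over the alternatives). The 10 inhibitory receptors had a median of 0.52, with 2 higher and 0 lower adjusted over the list alone (adjusted p = 0.00283, and adjusted p = 0.343 with an estimated correlation, 0.00219 to 0.664 over the alternatives), with Nt5e at 1.90 ± 0.42. The 19 glycolysis genes had a median of 0.21 (adjusted p = 0.0334, and adjusted p = 0.951 with an estimated correlation, 0.00219 to 0.951 over the alternatives). None of these lists was called with an estimated correlation, with or without a slide block. Cholesterol genes were called with a block only (adjusted p = 0.0745 without one, and 0.0208 to 0.969 over the alternatives, and adjusted p = 0.664 with both a slide block and an estimated correlation).

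Steps between neighbouring effector subsets placed most of the change between early and intermediate cells. Between intermediate and early effector cells limma called 0 of 11776 genes (305 at an unadjusted p under 0.05), and 31 with slide as a block (13 higher and 18 lower) or 8 with a replicate block. With a slide block Ntrk3 (2.94 ± 0.22) and Sipa1l2 (2.55) were among the higher genes, and Ifngr2 (−2.71), Foxp3 (−2.67 ± 0.23) and She (−2.60) among the lower genes in intermediate cells, all chosen after their values were seen. Between late and intermediate effector cells limma called 0 of 11819 genes (36 at an unadjusted p under 0.05) and 0 with slide (202) or replicate number (78) as a block. Over 10887 genes the intermediate-minus-early change correlated at 0.768 between replicates and the late-minus-intermediate change at 0.144. Genes are not independent replicates.

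Late effector memory cells were compared with cells labelled central memory to see whether memory subsets part in the same way. Il17a and Il23r were called higher in late effector memory cells, and Foxp3 lower with a block only. Of 11150 genes limma called 2 higher and 0 lower, with 196 at an unadjusted p under 0.05. The genes were Il17a, at least 7.32-fold higher (4.66 ± 0.44, adjusted p = 0.00455), and Il23r, the receptor that sustains Th17 cells, at least 10.4-fold higher (5.32 ± 0.66, adjusted p = 0.0349). Both were above background in late effector memory cells alone, at 0.25 and −0.46 for Il17a and 1.18 and −0.37 for Il23r. The Il17a call was lost without central memory replicate 1 (4.69) or 2 (4.63), after normexp correction (1.47), with the median of each array as the scale (4.67), with only the arrays of the compared groups (4.66), without both libraries that ran against replicate 1 (4.63) and without the arrays of slide 2 (4.66). The Il23r call was lost without central memory replicate 1 (5.44) or 2 (5.20), without late effector memory replicate 1 (4.55), without early effector memory replicate 1 or 2 or naive replicate 1 or 2 (5.32 each), and after normexp correction (1.95). It was also lost with the median of each array as the scale (5.33), without the filter on dim probes, with only the arrays of the compared groups and without the arrays of slide 2 (5.32 each), and without both libraries that ran against replicate 1 (5.20). The number called higher was 0 without central memory replicate 1 or 2 and 1 without early effector memory replicate 1 or 2 or naive replicate 1 or 2. It was 4 without intermediate effector replicate 1 or 2 and 9 without late effector memory replicate 2, and 1 gene was lower without late effector memory replicate 1.

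A slide block called 14 genes higher and 1 lower in late effector memory cells, and with a replicate block 9 and 1. Besides Il17a and Il23r these included Cpe (4.21 ± 0.29, adjusted p = 0.00702), Ccr6 (2.87 ± 0.32), Hlf (2.76 ± 0.29) and Dock5 (1.96 ± 0.17) among the higher genes, and Foxp3 (−3.01 ± 0.23), the lower gene. They were chosen after their values were seen. Of 13 Th2 and Th17 genes 2 rose and 0 fell (5 and 0 adjusted over the list alone, 4 and 0 with slide as a block, median 1.03, adjusted p = 2.82e-19), and the list was also called with an estimated correlation, with or without a slide block (adjusted p = 0.0394 without one, its highest value over the alternatives). The 18 naive and quiescence genes had a median of −0.53 (−0.96 on slide 1 and −0.11 on slide 3, adjusted p = 2.48e-11, and adjusted p = 0.481 with an estimated correlation, 1.06e-14 to 0.670 over the alternatives). The 11 regulatory T cell genes had a median of −0.52 (−0.15 and −0.88 on slides 1 and 3), with 0 higher and 2 lower adjusted over the list alone and 1 lower with a slide block (adjusted p = 4.11e-06, and adjusted p = 0.504 with an estimated correlation, 1.33e-07 to 0.504 over the alternatives). The 18 effector molecules had 0 members called, also adjusted over the list alone, and a median of −0.63 (adjusted p = 9.88e-05, and adjusted p = 0.481 with an estimated correlation, 3.26e-05 to 0.547 over the alternatives), with Klrg1 at −1.93 ± 0.90 and Tnf at 1.45 ± 0.59. The 28 cell cycle genes had a median of −0.23 (−0.48 on slide 1 and 0.04 on slide 3, adjusted p = 3.83e-05, and adjusted p = 0.620 with an estimated correlation, 5.50e-05 to 0.670 over the alternatives). These last 4 lists were not called with an estimated correlation, with or without a slide block.

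Steps between neighbouring memory subsets were compared as well. Between late and early effector memory cells limma called 1 of 11401 genes (180 at an unadjusted p under 0.05), Il17a, at background in early effector memory cells and at least 7.64-fold higher (4.67 ± 0.44, adjusted p = 0.00455), and 10 with slide as a block (9 higher and 1 lower) or 7 with a replicate block. With a slide block St6galnac2 (3.09 ± 0.29) was among the higher genes and Foxp3 (−3.14 ± 0.23) was lower, both chosen after their values were seen. The number called was 0 without early effector memory replicate 2, 2 without late effector replicate 1 or 2 or central memory replicate 1 or 2, 3 without late effector memory replicate 1 and 7 without late effector memory replicate 2. Between cells labelled early effector memory and central memory limma called 0 of 11184 genes (18 at an unadjusted p under 0.05), and 0 with slide (134) or replicate number (49) as a block. That step ran in opposite directions in the replicates, with a correlation of −0.572 over 10887 genes.

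The late-minus-early change was compared between memory and effector cells to ask whether the subsets part alike at both times. Over 10887 genes the group means correlated at a Pearson r of 0.292 and a Spearman rho of 0.265, and genes are not independent replicates. Single pairings gave a Pearson r of 0.419 and 0.361 with memory replicate 1, and 0.0103 and −0.106 with memory replicate 2. Without central memory replicate 1 the Pearson r was −0.03 and the Spearman rho −0.09. Foxp3 fell toward the late subset in both effector and memory cells with a slide block, and Il17a and Il23r were called toward the late subset in memory cells. For the difference of the changes limma called 0 of 12075 genes (156 at an unadjusted p under 0.05), 0 with a replicate block (405) and 4 with slide as a block, among them Cpe, Hbegf and She, chosen after their values were seen.

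Genes of fatty acid synthesis were followed in every comparison because the series concerns inhibition of that pathway. Camera did not call the list in any of the 5 main comparisons, at adjusted p = 0.333 or more over the alternatives of the list test. Of 17 tested genes 0 rose and 1 fell in effector against naive cells (0 and 1 adjusted over the list alone, 6 and 2 with slide as a block, median −0.14, adjusted p = 0.820), and 0 changed in memory against naive cells (1 fell with slide as a block, median −0.06, adjusted p = 0.586). In memory against effector cells 2 rose and 2 fell, also adjusted over the list alone, or 3 and 5 with slide as a block (median 0.22, adjusted p = 0.953), and the direction of the camera test was down against a median and mean above 0. The medians were 0.07 between late and early effector cells (adjusted p = 0.550) and 0.12 between late effector memory and central memory cells (adjusted p = 0.855), with 0 genes called. With slide as a block the median was 0.23 in effector against naive cells and −0.14 in memory against effector cells, and its sign depended on the block. Single enzymes did change. Acss2, which makes acetyl-CoA from acetate, fell in effector cells (−2.96 ± 0.61, adjusted p = 0.00903), a call lost without naive replicate 1 (−2.47). It rose in memory against effector cells (1.79 ± 0.43, adjusted p = 0.0199), a call lost without central memory replicate 1 (1.53), late effector memory replicate 1 (1.72), early effector replicate 2 (1.53), intermediate effector replicate 2 (1.62) or late effector replicate 2 (1.55), with the median of each array as the scale (1.91) and without the arrays of slide 2 (1.12). The mitochondrial carboxylase Acacb rose (1.16 ± 0.25) and the elongase Elovl6 fell (−1.05 ± 0.24) in memory against effector cells, and the desaturase Scd2 fell (−1.77 ± 0.44). With the median of each array as the scale the calls on Acacb (1.28) and Elovl6 (−0.93) were lost, and that on Acacb also with the mean of all probes (0.95), without both libraries that ran against replicate 1 (1.04) and without the arrays of slide 2 (0.94). Fasn, the synthase itself, was not called (0.43 ± 0.28). Scd2 and Fasn were chosen after their values were seen.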

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

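The tests of regulatory T cell genes other than Foxp3 and of the interleukin 17 genes against early effector memory 2 were chosen only after the result was seen.

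In memory cells the libraries labelled central memory 2 and early effector memory 2 ran against replicate 1. The step from one to the other correlated at −0.522 between the replicates over the 10947 genes used here. Over the 10887 genes tested in both late-minus-early comparisons, as given above, the value was −0.572. Over 10947 genes the step from central memory to early effector memory in replicate 1 correlated with the step from early to intermediate effector cells on slide 1 at 0.512, while the replicate 2 step correlated with it at −0.332, so an exchange of these labels may explain the pattern. The separate scan of central memory 2 also stays open, since a sort score of 100 genes on each side gave 0.643 for early effector memory 2 minus late effector memory 2, scanned together, midway between −0.2 and 1.484 in replicate 1. The difference of those distances was 0.002, with a range of −0.349 to 0.32 over 1000 resamples of genes. A difference between the donors of the replicates was not tested.

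Foxp3 was lower in late than in early effector cells and lower in late effector memory than in central memory cells with slide as a block. With that block Foxp3 was also lower in late than in early effector memory cells, both CD62L low by the sort. Taken by the labels, the fall in memory cells thus did not follow CD62L alone. The possible exchange of labels between central memory 2 and early effector memory 2 leaves this open in replicate 2. The 11 other tested regulatory T cell genes had a median shift of −0.904 on slide 1 and −1.005 on slide 2 between late and early effector cells, which restates the fall of their list and does not tell its source. Regulatory T cells among the CD62L high cells, which the CD127 negative gate of effector cells would not remove but the CD127 high gate of memory cells largely would, stay open: Ikzf2, Nrp1 and Gpr83 had a mean shift of −0.855 on slide 1 and −1.381 on slide 2 that hid opposite members. Ikzf2, the only 1 well above background on all 4 arrays, was higher by 0.693 and 0.493 and Gpr83 lower, at −2.354 and −2.709. Foxp3 was 3.79 and 2.67 in the libraries labelled central memory 1 and 2 despite the CD127 high gate, and conventional effector cells that transcribe part of this program under activation were not tested separately and stay a biological explanation.

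Il17a and Il23r were called higher in late effector memory cells, and the Th2 and Th17 list had a median of 1.475 on slide 1, which an exchange of labels between central memory 2 and early effector memory 2 would not touch. That exchange stays open as a contribution: Il17a, Il23r and Ccr6 were higher in late effector memory 2 than in early effector memory 2 with a median difference of 4.069, but they were picked from the pattern and only 1 of them was well above background in both libraries. Gamma delta T cells, which also make interleukin 17 and which the CD4 gate would largely remove, could be a source. The median of 5 of their marker genes was 0.706 on slide 1 and 0.581 on slide 3. Cd163l1 was higher by 2.016 and 2.274 and 5830411N06Rik by 4.15 and 2.694, while Sox13 (−0.135 and −0.029) and Blk (−0.324 and −0.212) were not, and only 2 of the 5 genes were well above background on all 4 arrays. A Th17-like memory population among the B5 cells is the biological explanation that stays open.

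Between memory and effector cells, the number of genes called was set against other splits of the 12 arrays into 6 and 6. Among 100 of the 462 splits, only the real one called as many genes as its 2545 in a fit of 2 groups alone. The highest other called 2119. The fit with all 7 groups, which called 907 higher and 645 lower, was not split. That other split put 5 of the 6 replicate 2 arrays on one side, and the split on replicate number itself called 6383, so the arrays also hold a structure by replicate. Among the 40 drawn splits with 3 arrays of each number on each side, as the real one has, the highest other called 2. In replicate 2 the effector arrays share slide 2 and the memory arrays share slide 3, so there the splits cannot tell cell type from slide.

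With slide as a block 4 genes differed in their late-minus-early change between memory and effector cells, by a test of the difference itself, and 3 of them are given here. Cpe differed by 4.882, with changes of 4.81 and 3.604 in memory and −0.78 and −0.569 in effector cells. Hbegf differed by 4.123, with 2.919 and 2.38 in memory and −1.123 and −1.825 in effector cells, but it was well above background on only 4 of the 8 arrays, so these are no exact changes. She differed by 3.334, with 0.894 and 1.656 in memory and −2.038 and −2.081 in effector cells. Without a block limma called 0 genes, with an adjusted p of 0.793 for Cpe.

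Probes without a gene symbol, which no comparison used, changed too. Of 8901 such probes 233 were higher and 275 lower in effector against naive cells. Of 8139 probes 75 were higher and 32 lower in memory against naive cells, and of 8747 probes 258 were higher and 265 lower in memory against effector cells. Between late effector memory and central memory cells 2 were higher and 1 lower of 6989. Groups of 2 arrays are too small for a test of single outlying samples.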

How the results depend on the processing

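Leaving out both libraries that ran against replicate 1, leaving out the 3 arrays of slide 2, the deposited values with a slide block, leaving out saturated genes, scaling to the median over genes well above background on all arrays, and the list tests with both a slide block and an estimated correlation were chosen after seeing the data. Data were simulated from the fit with a slide block, with its slide effects and independent noise, and there many changes were missed without a block. Of 4-fold changes 16.4% were recovered for effector against naive, 14.9% for memory against naive and 64.2% for memory against effector cells. For late against early effector and late effector memory against central memory cells 0 were recovered. Of 8-fold changes 56.1%, 48.5%, 84.8%, 15.2% and 21.2% were recovered in that order. A slide block recovered 76.1%, 85.1%, 94%, 80.6% and 80.6% of 4-fold changes. The data were simulated from that model, so its gain was set in advance. The simulation does not tell how many changes were missed in the arrays. Dim genes limit the folds, since signal counts as well above background only from log2 levels of −5.24 to −2.49, depending on the array. Counts are given as higher and lower. Except where fewer genes or arrays were used, the cause was not tested.

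Over the non-leave-one-out alternatives, 251 pairs of a named gene and a comparison gave 3591 values with the same direction and side of the threshold, 138 that lost the call, 195 that gained one, 15 that moved and 0 that reversed. Averaging all probes of a gene and leaving out saturated genes moved no count by more than 1.5 times.

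Normexp background correction, which compresses changes of dim genes, gave 580 higher in effector against naive cells, 190 higher in memory against naive cells, 0 in late effector memory against central memory cells, 0 between late and early effector memory cells, and 118 genes higher in both effector and memory cells. Quantile normalization gave 1575 and 1068 in memory against effector cells, 11 higher in late effector memory against central memory cells, 917 lower in effector and 88 lower in memory cells against naive, 2 between early effector memory and central memory cells, 15 between late and early effector memory cells, 3 for the difference of late-minus-early changes and 71 lower in both.

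The median of each array as the scale gave 454 and 216 in effector against naive, 254 and 26 in memory against naive, 453 and 296 in memory against effector cells, 0 higher in late effector memory against central memory cells, 0 between late and early effector memory cells, 137 and 21 in both, and a fatty acid synthesis median of −0.15 between late and early effector cells. It moved the median of all genes from −0.07 to −0.21 in effector against naive, from 0.08 to 0.20 in memory against effector and from −0.07 to −0.29 in late against early effector cells. The median over genes well above background on all arrays gave 1 higher in late against early effector cells, 84 lower in memory against naive and 5 between late and early effector memory cells.

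Without the filter on dim probes 1 gene was higher in late effector memory against central memory cells, 35 lower in memory against naive, the Spearman rho of the late-minus-early changes was −0.034 and the fatty acid synthesis median in memory against naive cells was 0.077. Genes well above background on all 14 arrays, fewer in number, gave 297 and 268 in effector against naive, 131 and 8 in memory against naive, 540 and 247 in memory against effector cells, 0 higher in late effector memory against central memory cells, 0 between late and early effector memory cells and 89 and 7 in both. This filter took the share higher among called genes to 52.6% in effector against naive and 68.6% in memory against effector cells.

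A slide block gave 2631 and 1836 in effector against naive, 1328 and 619 in memory against naive (68.2% higher), 1755 and 2313 in memory against effector, 8 and 5 in late against early effector, 14 and 1 in late effector memory against central memory cells, 31 between intermediate and early effector, 10 between late and early effector memory cells, 4 for the difference of late-minus-early changes, 937 and 420 in both, and fatty acid synthesis medians of 0.235 in effector against naive and −0.144 in memory against effector cells. Of its calls, 1358, 565 and 1430 in the first 3 comparisons were the same genes in the same direction as without it. Slide as a random block, at a correlation of 0.698, gave 2056 and 1599, 1219 and 502 (70.8% higher), 1615 and 1698, 23 and 17, and 49 and 3 in the 5 main comparisons, 87 between intermediate and early effector, 1 between late and intermediate effector, 55 between late and early effector memory cells, 13 for the difference, 835 and 344 in both, and fatty acid synthesis medians of 0.146 in effector against naive and −0.055 in memory against effector cells.

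The replicate number as a block gave 1726 and 1795 in effector against naive (49% higher), 868 and 248 in memory against naive (77.8% higher), 2564 and 1754 in memory against effector, 3 and 1 in late against early effector, 9 and 1 in late effector memory against central memory cells, 8 between intermediate and early effector, 7 between late and early effector memory cells and 619 and 200 in both. It moved no other count by more than 1.5 times. Among named genes it ended 0 calls and added 21.

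Only the arrays of the compared groups gave 0 higher in late effector memory against central memory, 275 lower in effector against naive, 0 between late and early effector memory cells and 23 lower in both. Deposited values gave 1844 and 1233 in memory against effector, 19 higher in late effector memory against central memory, 1167 lower in effector and 149 lower in memory cells against naive, 10 between late and early effector memory cells, 1 for the difference and 129 lower in both. With a slide block as well they gave 2761 and 2821 (49.5% higher), 1851 and 1504 (55.2% higher), 2791 and 2522, 110 and 133, and 94 and 8 in the 5 main comparisons, 284 between intermediate and early effector, 81 between late and early effector memory cells, 114 for the difference, 1144 and 1037 in both, and fatty acid synthesis medians of 0.091 in effector against naive and −0.042 in memory against effector cells.

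Without both libraries that ran against replicate 1 the counts were 472 and 415 in memory against effector, 0 higher in late effector memory against central memory and 0 between late and early effector memory cells, with fatty acid synthesis medians of 0.263 in memory against naive and −0.05 in late effector memory against central memory cells. Without the arrays of slide 2 they were 482 higher in memory against effector (40.1% higher), 0 higher in late effector memory against central memory and 0 between late and early effector memory cells, with fatty acid synthesis medians of 0.22 in effector against naive, −0.294 in memory against effector and −0.005 in late against early effector cells.

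Leaving out each array in turn, where a lone array is assumed to vary like the other groups, gave 391 to 920 higher and 92 to 508 lower in effector against naive, 168 to 499 and 3 to 78 in memory against naive, 595 to 933 and 447 to 569 in memory against effector, 0 to 9 and 0 to 1 in late effector memory against central memory cells, 0 to 7 between late and early effector memory cells, and 105 to 353 higher and 0 to 59 lower in both. It gave 0 calls throughout in late against early effector cells, in the other steps and for the difference. The Pearson r of the late-minus-early changes ranged from −0.025 to 0.391 and the Spearman rho from −0.093 to 0.345. Fatty acid synthesis medians ranged from −0.482 to 0.004 in effector against naive, −0.116 to 0.221 in memory against naive, −0.123 to 0.542 in memory against effector, −0.405 to 0.46 in late against early effector and −0.19 to 0.363 in late effector memory against central memory cells.

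With an estimated correlation camera called 0 lists in effector against naive (13 at the preset), 4 in memory against naive (15), 0 in memory against effector (12), 0 in late against early effector (9) and 1 in late effector memory against central memory cells (5). Adding a slide block made these 0, 4, 0, 0 and 1, with regulatory T cell genes called and inhibitory receptors not called in memory against naive cells. After normexp alone it called 8 in the last.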

Other observations

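The list tests in this part were planned, except those with both a slide block and an estimated correlation, and the sex-linked genes were read after the slides were seen to part. The NK and CD8 list and the B cell list were called higher in memory cells without a block. Of 4 tested NK and CD8 genes 2 rose in memory against naive cells (3 adjusted over the list alone, median 2.64, or 0.65 with bounds), Ncr1, at least 4.26-fold higher, and Klrb1c, at least 3.13-fold higher. Against effector cells 3 of 4 rose (median 2.31, or 1.43 with bounds), among them Ncr1, which was well above background on 1 of the 6 effector arrays. Camera called the list in both comparisons, at adjusted p = 0.00996 against naive (0.293 with an estimated correlation, 0.0587 to 0.549 over the alternatives) and 0.00962 against effector cells (0.594 with an estimated correlation, 0.0209 to 0.594 over the alternatives). Against naive cells the call was lost under every alternative of the list test, including slide (0.132) and replicate number (0.0587) as a block. Against effector cells it was lost under every one but the slide block at the preset correlation (0.0731 with a replicate block). In this list only 1 member was tested in effector against naive cells, at −1.30. The Ncr1 and Klrb1c calls against naive cells were lost without naive replicate 1 (4.12 and 3.51) and without naive replicate 2 (3.59 and 3.77). Of 5 B cell genes 1 rose in memory against naive cells (median 0.92, or 0.89 with bounds, adjusted p = 0.0303, and adjusted p = 0.311 with an estimated correlation, 0.0879 to 0.549 over the alternatives) and 3 rose in memory against effector cells (adjusted p = 0.0441, and adjusted p = 0.607 with an estimated correlation, 0.0309 to 0.607), while in effector against naive cells the list was not called (median −0.04, adjusted p = 0.959). The B cell call against naive cells was also lost under every alternative of the list test. That against effector cells was lost under every one but the slide block at the preset correlation (0.172 with a replicate block). A slide block called 1 NK and CD8 gene and 1 B cell gene lower in effector against naive cells.

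Erythroid and platelet genes were higher than in naive cells in both effector cells (7 tested, 0 called or 2 adjusted over the list alone, median 1.56, adjusted p = 0.0104, 0.00815 to 0.383 over the alternatives) and memory cells (6 tested, 1 called or 4 adjusted over the list alone, median with bounds 2.03, adjusted p = 0.000161, 0.000267 to 0.380). Both calls were lost with an estimated correlation (0.146 and 0.110 without a block), and with slide as a block 3 genes were higher in effector and 5 in memory cells. Between late and early effector cells their median was 0.75 (adjusted p = 0.0444, 0.0658 with a replicate block, 0.0462 to 0.664 over the alternatives), not called after normexp or with an estimated correlation (adjusted p = 0.395), and they were not called in memory against effector cells (median 0.25, adjusted p = 0.830, with 4 genes higher and 1 lower with a slide block). Of 4 plasma cell genes 1 rose in memory against naive cells (median 1.53, adjusted p = 0.00839, and adjusted p = 0.110 with an estimated correlation, 0.00376 to 0.190), and the list had a median of 1.32 in effector against naive cells (adjusted p = 0.102). Slide as a block called 2 plasma cell genes higher in each of effector and memory against naive cells, and 1 lower in memory against effector cells. Between late and early effector cells the plasma cell list was called without a block (adjusted p = 0.0334, and adjusted p = 0.343 with an estimated correlation, 0.01 to 0.755 over the alternatives) but not with slide (0.492) or replicate number (0.141) as a block. The 10 myeloid genes tested had a median of 1.18 in memory against naive cells (0.63 with bounds, adjusted p = 0.0658) and were not called in effector against naive (median 0.46, adjusted p = 0.237) or memory against effector cells (adjusted p = 0.823). In the fit with a slide block 2 of them were higher and 1 lower, 4 higher and 0 lower, and 3 higher and 1 lower in effector against naive, memory against naive and memory against effector cells. Of the dendritic cell genes 1 was tested, at 0.46 in effector against naive cells. The 9 T lineage reference genes were not called as a list, with medians of 0.17, 0.11 and 0.05 in effector against naive, memory against naive and memory against effector cells (adjusted p = 0.765, 0.505 and 0.953), and a slide block called 3 higher, 1 higher, and 1 higher and 2 lower.

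The fatty acid oxidation, oxidative phosphorylation and lipid uptake lists were not called without a block. The 18 fatty acid oxidation genes had a median of 0.27 in effector against naive (adjusted p = 0.167, 0.0152 to 0.949 over the alternatives, called with a slide block and not with an estimated correlation as well, adjusted p = 0.271), 0.18 in memory against naive (adjusted p = 0.499) and −0.11 in memory against effector cells (adjusted p = 0.297), with 10 higher and 1 lower, 4 and 0, and 1 and 8 called with a slide block. The 26 oxidative phosphorylation genes had medians of 0.20, −0.004 and −0.20 in these comparisons (adjusted p = 0.354, 0.646 and 0.0842), with 7 genes higher, 0 called and 10 lower with a slide block. Both blocks called that list lower in memory than in effector cells, at adjusted p = 0.000143 with slide and 0.00628 with replicate number (0.000143 to 0.970 over the alternatives). The slide block called it higher in effector than naive cells (0.00322 to 0.984 over the alternatives). Both slide-block calls were lost with an estimated correlation as well, at adjusted p = 0.556 in memory against effector and 0.585 in effector against naive cells. With a slide block camera also called the list lower in late than in early effector cells (adjusted p = 0.0231, and 0.755 with an estimated correlation as well). It was called with that block between late effector memory and central memory cells too (adjusted p = 0.0292, and up to 0.979 over the alternatives). Lipid uptake and storage genes were not called, with a median of −0.15 and a mean of 0.05 in effector against naive cells (adjusted p = 0.603), 0.26 in memory against naive (adjusted p = 0.311) and 0.25 in memory against effector cells (adjusted p = 0.890), with 4 higher, 3 higher and 1 lower, and 4 higher and 3 lower with a slide block. Heat shock genes were not called without a block (adjusted p = 0.495, 0.897 and 0.304) and were called with a slide block in effector against naive (0.0152 to 0.984 over the alternatives) and memory against effector cells (0.00751 to 0.970), with 4 genes higher and 4 lower. Those calls were lost with an estimated correlation as well (adjusted p = 0.383 and 0.556). In effector against naive cells, immediate early genes had a median of −0.67 (adjusted p = 0.123, 0.000446 to 0.668 over the alternatives, called with a slide block but not with an estimated correlation as well, adjusted p = 0.232, 3 higher and 11 lower with a slide block), interferon-stimulated genes −0.34 (adjusted p = 0.880, 5 higher and 3 lower with a slide block) and homing receptors −0.29 against a mean of 0.32 (adjusted p = 0.959). In memory against naive cells, interferon-stimulated genes had a median of 0.19 (adjusted p = 0.105) and immediate early genes 0.11 (adjusted p = 0.505, 3 higher with a slide block).

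Sex-linked genes parted the replicate numbers. Ddx3y was 2.11 to 2.99 on the 7 replicate 1 arrays and −6.64 to −4.84 on the 7 replicate 2 arrays, and Xist was −5.47 to −3.72 and 0.571 to 1.573. Replicate number, donor sex and slide 1 against the others cannot be told apart in this design, because all replicate 1 arrays share slide 1.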
